A study of Arabidopsis thaliana with 9 samples.

How the data were processed

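The data are mRNA levels in detached rosette leaves of 30-day-old Arabidopsis thaliana plants, taken without infection, in 9 libraries. The 3 genotypes are the wild type Col-0 (WT), a line labelled as a knockout of VQ28 (VQ28KO12) and a line labelled as overexpressing VQ28 (VQ28OE9), with 3 libraries each, grouped by the sample titles. Per the labels' protocols, poly(A) RNA was selected and the libraries were strand-marked with dUTP and sequenced in pairs. The labels do not say whether the 3 libraries of a genotype came from separate plants, so p-values measure the spread between these libraries, which may be technical. How the knockout was made, and so whether VQ28 mRNA should be missing, is not given in the sources used here.

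The authors deposited 1 table with 33610 genes, each with an FPKM (fragments scaled to gene length and library size) and a whole-number count per library, per the file headers. The aligner, the counting tool and the genome build are not given in the sources used here, and neither is whether the counting used the strand. The deposited counts were treated as estimated counts, because low values pile up at multiples of 4: between 48.7% and 57.0% of the values from 1 to 16 are multiples of 4, against 25% by chance. A sequenced fragment is therefore worth about 4 of the deposited count units, and counts are called units below. The authors list a gene without counts at an FPKM of 0.0001. The library totals were 64552605 to 95223547 units, and each library had between 20510 and 20956 genes above 0. Genes carry locus identifiers, of which 28932 were matched by locus tag to the TAIR10.1 gene table for names. The gene table carries no VQ numbers, so VQ28 was taken as AT4G20000 from the published numbering of the family. Coordinates are those of the deposited table.

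The test planned for FPKM alone was limma on log2(FPKM + 1), with the rule that raw counts per sample, where present, take its place. Whole-number counts were present, so the main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, TMM normalization) on the units as deposited. Because these are estimated rather than raw counts, applying the rule to them was a choice made with the file at hand. The limma test is given as an alternative. All 9 libraries were fitted together with 1 mean per genotype. The 16050 genes with a mean FPKM of at least 1 over the 9 libraries were tested, two-sided, and a gene is said to have changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the fitted log2 fold change divided by the square root of the F statistic. Means and SDs of levels are in FPKM as the authors scaled them. A fold against a genotype at 0 in all 3 libraries is given as a lower bound, set against 3 fragments, or 12 units, in each library. Where a genotype's mean lay under 12 units but not at 0, the ratio of normalized units is given with a 95% exact binomial interval on fragments, which covers counting error only.

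Before the data were examined, 19 gene lists were fixed: salicylic acid defence, jasmonate synthesis and response, ethylene response and defensins, camalexin and indole glucosinolates, aliphatic glucosinolates, pattern-triggered immunity, abscisic acid and water deficit, photosynthesis, leaf senescence, rapid touch, wound and cold response, circadian clock, heat shock proteins, flavonoid and anthocyanin synthesis, the VQ family, and markers of guard cells, epidermis, vascular tissue, dividing cells and flower organs. The WRKY family, taken by symbol from the gene table, was fixed with them. Each list with at least 5 tested members was tested with camera at a preset correlation and with an estimated correlation, and with fry, adjusted over the lists of a comparison. The other lists are given as counts. GO terms, as the deposited table gives them, with 10 to 500 tested members were tested with a one-sided hypergeometric test against the tested genes with a term. This test takes genes as independent and, unlike camera with an estimated correlation, makes no allowance for genes that vary together.

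The genes named were also set by a rule fixed at that point. For each line against WT these were VQ28, the 8 largest rises and 8 largest falls in log2(FPKM + 1) among changed genes with a mean FPKM of at least 5 in the higher genotype and libraries that did not overlap, and up to 3 changed members of each list. Where no member changed, the member with the smallest p is given as a value. Between the lines, 5 rises and 5 falls were taken. For the fold changes of both lines against the same WT libraries, all 9 libraries were simulated 100 times from 1 mean per gene, with each gene drawn independently.

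The steps were tested on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold among the 16050 genes. For VQ28OE9 against WT, 50.0% of the 2-fold and 92.0% of the 4-fold changes were recovered, and 5.33% of the calls were false. For VQ28KO12 against WT, 57.0% and 95.0% were recovered, with 6.17% false calls. For VQ28OE9 against VQ28KO12, 56.0% and 96.0% were recovered, with 7.32% false calls. Each comparison was simulated in a single run, with genes drawn independently from the fitted model. The shares of false calls therefore do not measure those among the real calls. The alternatives tried were limma 3.58.1 on log2(FPKM + pseudocount) with 3 pseudocounts, quantile normalization or sample weights, DESeq2 1.42.0, median-of-ratios factors, other filters on low values, only the 6 libraries compared, the replicate number as a block, other term sizes, and leaving out each library in turn. Dividing the units by 4 and leaving out organelle genes or genes with a gap between replicates, leaving out 2 libraries that stand apart, leaving VQ28 out of the VQ family, and setting each line against its own WT libraries were added after seeing the data. Figures were drawn with matplotlib 3.10.9.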

Results

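Leaf mRNA was compared between WT, the line labelled VQ28KO12 and the line labelled VQ28OE9, with 3 libraries each. The total count units were 71023343, 67923024 and 64552605 in the WT libraries 1 to 3, 76990110, 64845109 and 95223547 in those labelled VQ28KO12, and 70542580, 76743510 and 77172452 in those of VQ28OE9. VQ motif proteins, to which VQ28 belongs, are plant cofactors that bind WRKY transcription factors.

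The first question was whether the target gene follows the labels. VQ28 (AT4G20000, chromosome 4, 10838310 to 10839142, plus strand, annotated as a VQ motif-containing protein) stood at 6244, 4665 and 5942 FPKM in the 3 VQ28OE9 libraries, a mean of 5620 ± 839 (SD, n = 3). In WT it stood at 8.70, 0.456 and 6.72 FPKM, a mean of 5.29 ± 4.30. It rose by 10 ± 1.67 (SE) on the log2 scale in VQ28OE9 against WT (edgeR adjusted p = 0.0215), with all 3 libraries higher. In the libraries labelled VQ28KO12 it stood at 8.36 and 10.2 FPKM in replicates 1 and 2 and had 0 units in replicate 3, which allows up to 3 fragments. VQ28KO12 did not differ detectably from WT, with a log2 fold change of 0.14 ± 1.17 (adjusted p = 1). The exact two-sided permutation p was 0.9 for that pair and 0.1 for each pair with VQ28OE9, where 0.1 is the smallest that 3 against 3 libraries can give. The level in replicates 1 and 2 goes against the knockout label as far as mRNA can show it, so these libraries are named by their label throughout. The call in VQ28OE9 against WT was lost without WT replicate 1 or 3 (adjusted p = 0.0638 in each) and without VQ28OE9 replicate 1 (0.0695), while the log2 fold change stayed between 9.49 and 10.6.

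**Figure D1:**
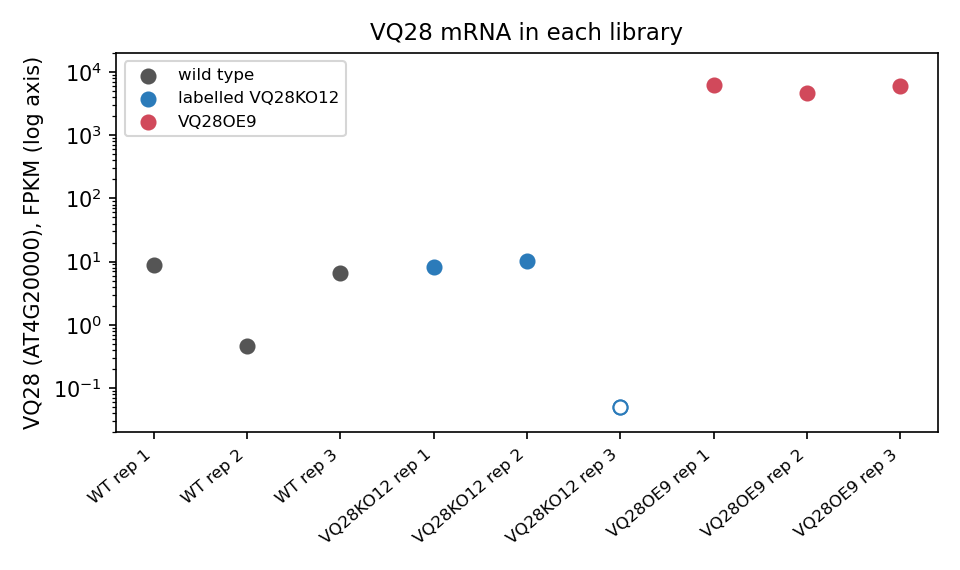
VQ28 mRNA in FPKM, on a log axis, in each of the 9 libraries, 1 point per library coloured by genotype; the open point marks the library with 0 units, drawn at the bottom because a log axis has no 0. The VQ28OE9 libraries stand at 4665 to 6244 FPKM, against 0.456 to 8.70 in WT.

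The comparison of VQ28KO12 with WT asks what changed in the line labelled as a knockout. AT3G42658.1, a locus that the gene table names SADHU3-2, a non-coding retrotransposon (chromosome 3, 14749400 to 14750294, minus strand), had 681, 402 and 760 units in the libraries labelled VQ28KO12 and 0 in each WT library. It was at least 41.9-fold higher (adjusted p = 0.000619). It was the only gene of 16050 that changed by edgeR. At an unadjusted p under 0.05 there were 808 genes, against 802 by chance, and DESeq2 called 39 genes. Without the library labelled VQ28KO12 replicate 2 edgeR called 4 genes and without VQ28OE9 replicate 2 it called 3, AT3G42658.1 among them. No member of any of the fixed lists changed.

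List members with the smallest p in VQ28KO12 against WT are given as values. The salicylic acid synthesis gene ICS1 stood at 4.34 ± 0.299 FPKM against 6.35 ± 0.431 in WT (adjusted p = 0.75), and the abscisic acid receptor gene PYL4 at 20.3 ± 2.85 against 10.8 ± 2.09 (0.749). The chaperone gene HSP101 stood at 37.8 ± 9.22 against 23.7 ± 1.65 (0.86) and the guard cell kinase gene HT1 at 3.23 ± 0.201 against 1.88 ± 0.396 (0.861). TAT3, TGG1, RLP23, PORB, SAG13 and NHL3 had log2 fold changes of -0.53, -0.50, -0.77, 0.35, -1.19 and -0.42. GRP8, PAP1, VQ29, ATML1, AHA3, CDKB2;1 and WRKY75 had log2 fold changes of 0.44, -0.78, -0.91, 0.48, -0.21, -0.46 and -1.43. PDF1.2c and CYP71A12 stood at 0.422 and 0.217 FPKM against 4.05 and 1.04 in WT.

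By camera with a preset correlation, 7 lists moved in VQ28KO12 against WT. Salicylic acid defence (adjusted p = 0.000458), leaf senescence (0.00156), jasmonate synthesis and response (0.0265), the WRKY family (0.0348) and camalexin and indole glucosinolates (0.0489) lay lower, and heat shock proteins (0.00183) and guard cell markers (0.0142) higher. With an estimated correlation none of the 7 was called, with adjusted p = 0.63, 0.213, 0.694, 0.694, 0.694, 0.63 and 0.213 in that order. By fry no list was called in this comparison, with a lowest adjusted p = 0.292. In salicylic acid defence, 19 of the 20 tested members had a negative log2 fold change, with a median of -0.33. Adjusted over the list alone, 1 member was lower in salicylic acid defence, 1 was higher in each of heat shock proteins, guard cell markers and epidermis markers, 1 was higher and 1 lower in abscisic acid and water deficit, and the other lists had 0. The 7 lists became 2 without the library labelled VQ28KO12 replicate 1, 4 without WT replicate 2 and 11 without WT replicate 3. Median and mean differed in sign for rapid touch, wound and cold response, which was not called.

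In VQ28OE9 against WT, 370 genes changed, 220 higher and 150 lower, and 238 of them by at least 1 on the log2 scale. AT1G09500, an NAD(P)-binding protein gene, rose to 43.3 ± 25.7 FPKM from 3.11 ± 0.920 in WT, a log2 fold change of 3.78 ± 0.40 (edgeR adjusted p = 0.011). The cytochrome P450 gene CYP81D8 rose to 53.8 ± 14.1 from 7.12 ± 3.63 FPKM (2.90 ± 0.38, adjusted p = 0.011). PDF1.2a, a plant defensin gene and a common marker of jasmonate and ethylene signalling, fell to 0.131 ± 0.226 from 20.4 ± 13.4 FPKM (adjusted p = 0.0128). It had 14 units in all in VQ28OE9 and 1876 in WT, a ratio of 150 with a 95% exact binomial counting interval of 51 to 484. DIN11, an oxygenase gene, fell to 1.81 ± 1.01 from 26.0 ± 9.74 FPKM (-3.86 ± 0.53, adjusted p = 0.0127).

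The other largest rises were AT4G28703, a cupin gene with 737 units in all against 18 in WT (a ratio of 36.5, counting interval 15.8 to 152), and on the log2 scale AT1G36622 by 2.66, AT1G53625 by 2.40, AT1G67920 by 2.25 and AT4G33467 by 2.22. The other largest falls were GT72B1 (AT4G01070), a UDP-glycosyltransferase gene, with a log2 fold change of -6.18, AT2G27228 with -4.68, AT3G16670 with -3.90, ATCSLA15 with -3.77, AT1G54010 with -2.58 and CYP71A13, an enzyme gene of camalexin synthesis, with -2.39. GT72B1 had 130 units in the library labelled VQ28KO12 replicate 2 and 17510 and 22417 in replicates 1 and 3. AT2G27228 overlaps AT2G27230, and AT1G67920, NHL3, HSP101, RLP23 and CDKB2;1 overlap AT1G67930, AT5G06310, AT1G74300, AT2G32670 and AT1G76530, so their levels are uncertain; so are those of PDF1.2a and PDF1.2c, which are close copies.

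**Figure D2:**
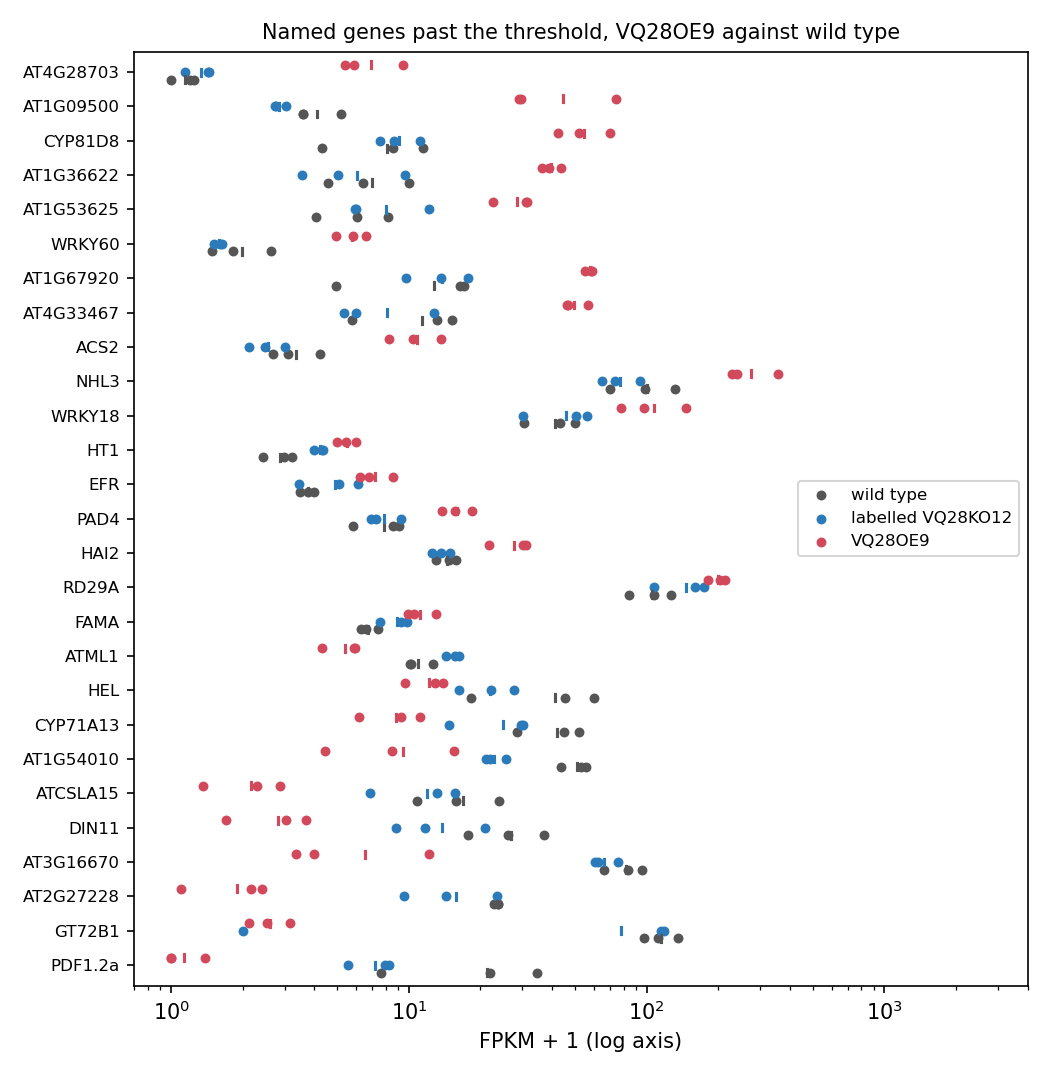
FPKM + 1, on a log axis, of the 27 named genes other than VQ28 that changed in VQ28OE9 against WT, with 1 point per library and a tick at the mean of the 3 libraries of a genotype. Genes are ordered by log2 fold change, from AT4G28703 to PDF1.2a, with 27.4 FPKM of AT1G53625 in VQ28OE9 against 5.09 in WT.

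Defence lists were described member by member for VQ28OE9 against WT. In pattern-triggered immunity 2 of 25 tested members rose, WRKY18 (1.39 ± 0.29 on the log2 scale) and the bacterial elongation factor receptor gene EFR (1.15 ± 0.25), none fell, and 10 were higher adjusted over the list alone. In salicylic acid defence 1 of 20 rose, the regulator PAD4 (14.9 ± 2.33 against 6.82 ± 1.76 FPKM), and 6 were higher adjusted over the list alone. In the WRKY family 2 of 38 rose, WRKY60 (2.27 ± 0.39) and WRKY18, and 12 were higher and 1 lower adjusted over the list alone. In ethylene response and defensins 1 of 19 rose, the ethylene synthesis gene ACS2 (2.05 ± 0.31), and 3 fell. Those 3 were PDF1.2a, HEL (-1.87 ± 0.39) and PDF1.2c, which was at 0 units in all 3 VQ28OE9 libraries and at least 11.8-fold lower (adjusted p = 0.0432). PDF1.2c lies outside the naming rule here and was chosen after its values were seen. VQ28KO12 also lay below WT in these 3 genes, though none passed. PDF1.2a stood at 6.23 against 20.4 FPKM, HEL at 21.1 against 40.1 and PDF1.2c at 0.422 against 4.05. Set against VQ28KO12, PDF1.2c in VQ28OE9 was at least 1.26-fold lower (edgeR adjusted p = 0.129). Part of these falls may thus lie in the shared WT libraries. Adjusted over the list alone, 2 members of that list were higher and 7 lower. In camalexin and indole glucosinolates 1 of 19 fell, CYP71A13, as it did adjusted over the list alone. None of the 28 members of jasmonate synthesis and response changed, and TAT3 stood at 967 ± 183 against 1520 ± 109 FPKM (adjusted p = 0.0863).

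Abiotic, cell type and VQ family lists were described in the same way for VQ28OE9 against WT. In abscisic acid and water deficit 2 of 22 rose, the phosphatase gene HAI2 (0.96 ± 0.15 on the log2 scale) and RD29A (198 ± 15.7 against 104 ± 20.8 FPKM), and 11 were higher and 1 lower adjusted over the list alone. In rapid touch, wound and cold response 1 of 15 rose, NHL3 (275 ± 71.6 against 99.0 ± 30.5 FPKM), and 4 were higher adjusted over the list alone. Among guard cell markers the kinase gene HT1 (1.22 ± 0.23) and the stomatal regulator FAMA (0.80 ± 0.16) rose, 2 of 5, and 3 were higher adjusted over the list alone. Of the 2 tested epidermis markers ATML1, an epidermal homeobox gene, fell by 1.21 on the log2 scale (4.38 ± 0.939 against 9.96 ± 1.44 FPKM), also adjusted over the list alone. In the VQ family, which holds the overexpressed gene, VQ28 alone rose of 20, and 5 were higher adjusted over the list alone.

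No member changed in VQ28OE9 against WT in 8 further lists with tested members. These were leaf senescence (2 of 15 higher adjusted over the list alone), aliphatic glucosinolates (1 of 18 lower), dividing cell markers (1 of 2 lower), and photosynthesis, circadian clock, heat shock proteins, flavonoid and anthocyanin synthesis and vascular markers with 0 each; no flower organ marker was expressed enough to be tested. Their members with the smallest p were ORE1 (1.73, adjusted p = 0.0589), TGG1 (-0.75, 0.0619), CDKB2;1 (-0.90, 0.169), RBCS1A (-0.45, 0.094), TOC1 (0.73, 0.156), HSP17.6II (-1.44, 0.201), CHI (-0.65, 0.212) and XCP1 (-0.43, 0.634).

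**Figure D3:**
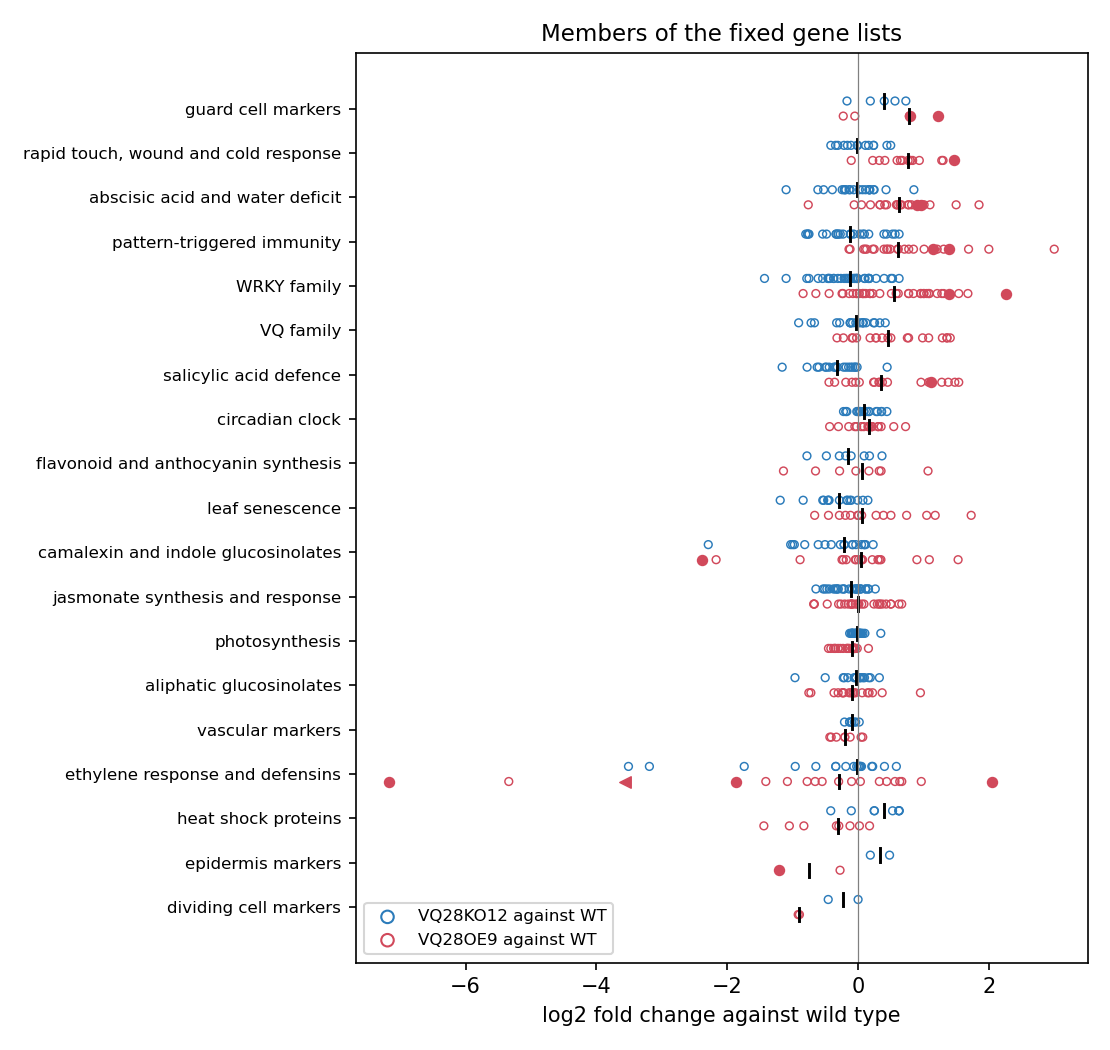
Log2 fold changes against WT of the tested members of each fixed list except VQ28, with 1 point per gene, filled where the gene changed (adjusted p under 0.05), blue for VQ28KO12 and red for VQ28OE9; black ticks are list medians and the triangle is PDF1.2c at its bound of -3.56. In VQ28OE9 the medians of abscisic acid and water deficit and of pattern-triggered immunity are both 0.62.

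By camera with a preset correlation, 10 lists moved in VQ28OE9 against WT. Pattern-triggered immunity (adjusted p = 3.72e-09), abscisic acid and water deficit (4.13e-08), rapid touch, wound and cold response (4.81e-07), the WRKY family (8.56e-07), the VQ family (7.82e-05), salicylic acid defence (0.000255) and guard cell markers (0.0123) lay higher. Photosynthesis (0.0123), heat shock proteins (0.0317) and ethylene response and defensins (0.032) lay lower. With an estimated correlation none was called, with adjusted p = 0.34, 0.26, 0.34, 0.34, 0.404, 0.389, 0.26, 0.691, 0.53 and 0.53 in that order. By fry, abscisic acid and water deficit and guard cell markers moved one way on balance (adjusted p = 0.0375 each). Without VQ28 the VQ family had a preset adjusted p = 0.000503 and an adjusted p = 0.472 with an estimated correlation. The median, mean and test differed in sign for jasmonate synthesis and response, camalexin and indole glucosinolates, and flavonoid and anthocyanin synthesis, none of them called.

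GO terms were tested for the genes that changed in VQ28OE9 against WT. Among the higher genes 4 terms passed: response to salicylic acid (10 genes against 1.15 expected by chance, hypergeometric adjusted p = 0.000266), response to chitin (10 against 1.46, 0.00126), cellular response to hypoxia (13 against 2.73, 0.00156) and response to abscisic acid (16 against 4.57, 0.00466). Among the lower genes 5 terms passed. Auxin efflux held 4 genes against 0.12 expected (adjusted p = 0.00578), and xyloglucan metabolic process held XTH31, XTH32, TBL27 and RWA4 (4 against 0.268, 0.0342). Kinase activity (11 against 2.27), O-acetyltransferase activity (4 against 0.249, all of the TBL family) and auxin efflux transmembrane transporter activity (3 against 0.102) were the others. With terms of 20 to 200 genes, 2 of the higher and 2 of the lower terms passed, because the other passing terms lie outside these sizes. The p-values take genes as independent, so they overstate the evidence where the genes of a term vary together. The cell wall genes were named from their terms after the values were seen.

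WT replicate 3 and VQ28OE9 replicate 3 stood apart on the second principal component (16.7% of the variance), at -33.6 and -37.8, with the other libraries between -7.6 and 22.4. WT replicate 3 also held 122 units of the 18S ribosomal RNA gene AT2G01010, against at least 20000 in every other library. Without both libraries 94 genes changed, 71 of them among the 370, and VQ28 kept a log2 fold change of 10.2 but lost its call (adjusted p = 0.0786). The count of 370 depended on single libraries. It was 103, 157 and 110 without WT replicates 1, 2 and 3, 46, 135 and 234 without VQ28OE9 replicates 1, 2 and 3, 199 and 246 without the libraries labelled VQ28KO12 replicates 1 and 3, and 163 when only the 6 libraries compared were fitted. DESeq2 called 1358 genes, with all 370 among them. Of the 27 named changes other than VQ28, the 6 in AT1G09500, CYP81D8, AT4G28703, AT3G16670, DIN11 and ATML1 passed in each of the 23 or 24 alternative settings run for them, with adjusted p up to 0.0479. Each of the others was lost in at least 1, with adjusted p up to 0.158. They ranged from PDF1.2a, past in 23 of 24 settings, to RD29A in 12 of 24, GT72B1 in 10 of 23 and HEL in 10 of 24.

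The comparison of VQ28OE9 with VQ28KO12 sets the lines against each other. Here 1016 genes changed, 595 higher and 421 lower in VQ28OE9. AT1G09500 rose to 43.3 ± 25.7 from 1.85 ± 0.168 FPKM (4.57 ± 0.42 on the log2 scale, edgeR adjusted p = 0.00257), and IGMT3, an indole glucosinolate methyltransferase gene, to 24.6 ± 17.1 from 2.02 ± 0.791 FPKM (3.63 ± 0.73, 0.0224). QQS, a gene linked to starch content, was lower, at 0.148 ± 0.164 against 12.5 ± 1.38 FPKM, with 0.771 ± 0.473 in WT (adjusted p = 0.00533). It had 20 units in all against 1761, a ratio of 82.3 with a counting interval of 35 to 254. The cell wall enzyme gene XTH25 fell to 0.657 ± 0.333 from 17.0 ± 11.6 FPKM (-4.64 ± 1.1, 0.0347). VQ28, AT1G36622 and AT4G33467 (9.89, 2.96 and 2.82) were the other largest rises, and AT2G27228 and AT3G16670 (-4.03 and -3.55) were among the largest falls. AT3G42658.1, at 0 in WT, had 21 units in all in VQ28OE9 against 1843 in VQ28KO12, a ratio of 82 with a counting interval of 36.6 to 267 (adjusted p = 0.00221).

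Several fixed lists held more changed members between the lines than in VQ28OE9 against WT; the difference in number was not tested. In the WRKY family 12 of 38 tested members were higher in VQ28OE9 and none lower, among them WRKY60 (3.05 ± 0.41) and WRKY33 (1.75 ± 0.34), and 16 were higher and 1 lower adjusted over the list alone. In pattern-triggered immunity 8 of 25 were higher, such as the flagellin-induced kinase gene FRK1 (2.48 ± 0.48) and PROPEP3 (2.45 ± 0.43), and 12 adjusted over the list alone. In abscisic acid and water deficit 8 of 22 were higher, such as the abscisic acid synthesis gene NCED3 (1.43 ± 0.35) and HAI1 (1.72 ± 0.28), with 11 higher and 1 lower adjusted over the list alone. In salicylic acid defence 6 of 20 were higher, among them ICS1 (0.92 ± 0.14), SARD1 (1.63 ± 0.29) and CBP60G (1.92 ± 0.39), and 8 adjusted over the list alone. In leaf senescence 4 of 15 were higher, ORE1, NAP, WRKY6 and SAG21, and 6 adjusted over the list alone. These list members were named after their values were seen.

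Smaller lists between the lines went as follows. In rapid touch, wound and cold response 3 of 15 were higher, and 4 adjusted over the list alone. In jasmonate synthesis and response the lipoxygenase genes LOX3 and LOX4 were higher, 2 of 28, and 3 adjusted over the list alone. HSP101 (-0.75 ± 0.18) and HSP70 (-0.96 ± 0.21) were lower, 2 of 8 heat shock proteins, and 6 adjusted over the list alone. Of the epidermis markers ATML1 (-1.69 ± 0.17) was lower, 1 of 2, and both were lower adjusted over the list alone. In ethylene response and defensins 1 member was higher, ACS2, and 2 were lower, with 2 higher and 6 lower adjusted over the list alone, and in camalexin and indole glucosinolates CYP71A12 was higher and CYP71A13 lower, as adjusted over the list alone. MAM3 of aliphatic glucosinolates and PAP1 of flavonoid and anthocyanin synthesis were each the 1 higher member, also adjusted over the list alone, and VQ29 (1.99 ± 0.42) was the other higher VQ gene, with 7 adjusted over the list alone. Photosynthesis, circadian clock, guard cell, vascular and dividing cell markers had 0 by either count. These members, too, were named after their values were seen.

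By camera with a preset correlation 8 lists moved between the lines, all higher in VQ28OE9 except heat shock proteins: pattern-triggered immunity (adjusted p = 1.02e-09), the WRKY family (1.85e-08), salicylic acid defence (3.99e-08), abscisic acid and water deficit (1.15e-07), rapid touch, wound and cold response (4.25e-06), heat shock proteins (9.09e-05), the VQ family (0.000151) and leaf senescence (0.000394). With an estimated correlation none was called, with adjusted p = 0.238, 0.209, 0.209, 0.204, 0.322, 0.295, 0.376 and 0.204 in that order. By fry, 5 lists moved one way on balance: abscisic acid and water deficit and leaf senescence (adjusted p = 0.0218 each), salicylic acid defence (0.0303), the WRKY family (0.0359) and pattern-triggered immunity (0.0481). Without VQ28 the VQ family had a preset adjusted p = 0.000883 and an adjusted p = 0.521 with an estimated correlation. Median and mean differed in sign for flavonoid and anthocyanin synthesis, which was not called. Among the higher genes 31 GO terms passed, led by response to chitin (30 genes against 3.99 expected, hypergeometric adjusted p = 1.94e-15) and cellular response to hypoxia (36 against 7.47, 1.87e-12). Among the lower genes 18 passed, such as plant-type cell wall (16 against 3.74, 0.00066), with the expansin genes EXPA1 and EXPA6, and response to auxin (15 against 4.19, 0.00419), with IAA19 and IAA29. With terms of 20 to 200 genes, 19 terms passed among the higher and 13 among the lower genes. The genes of these terms were named after their values were seen. Hypergeometric p-values take genes as independent, while the estimated correlation was 0.42 within pattern-triggered immunity and 0.19 within the WRKY family. They therefore overstate the evidence, and no list was called once such correlation was estimated. The count of 1016 was 131 and 167 without the libraries labelled VQ28KO12 replicates 1 and 3, 326, 507 and 519 without VQ28OE9 replicates 1, 2 and 3, and 1957 with DESeq2. VQ28 lost its call without the library labelled VQ28KO12 replicate 1 (adjusted p = 0.061), and IGMT3, XTH25, AT1G36622, AT4G33467 and AT2G27228 each lost theirs without at least 1 of these libraries, with adjusted p up to 0.12.

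The last question was whether the lines share changes. Across 16049 genes other than VQ28, which are not independent replicates, the log2 fold changes of the lines against WT had a Pearson correlation of 0.235, which was 0.369 without WT replicate 1 and 0.0601 for genes with a mean FPKM of at least 5. Simulated unchanged lines against shared WT libraries gave 0.499 on average over 100 simulations, from 0.43 to 0.567. The covariance was 0.0471, against 0.0447 simulated (0.0376 to 0.0541), a difference of 0.00239 that lies within the simulated range. With each line set against its own WT libraries, 1 for one line and the other 2 for the other line, the correlation averaged -0.0714 over the 6 ways, from -0.196 to 0.0698, and the covariance -0.0216, from -0.0609 to 0.0199. Simulated unchanged lines gave correlations from -0.0832 to 0.0863 and covariances from -0.0136 to 0.0128. Single ways thus lay below the simulated range in correlation and on both sides of it in covariance. The average covariance lay below its range. The sign was the same for 55.1% of genes, against 66.6% simulated (65.8% to 67.6%), and with separate WT libraries for 45.5% on average (41% to 53%), against 49% to 51% simulated. The outcome thus depended on the WT libraries used, and part of any sharing may come from them. Lying beyond the simulated ranges decides nothing here. The simulated genes varied independently, while the real libraries shared deviations across genes, so the ranges are too narrow. AT3G42658.1 was the 1 gene past the threshold in both comparisons, which share the WT libraries where it was at 0. In VQ28OE9 it had 4, 9 and 8 units, under the floor of 12, so no direction or fold is given against WT.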

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

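Dividing the units by 4 and leaving out organelle genes, genes with a replicate gap, the libraries that stand apart (WT replicate 3 and VQ28OE9 replicate 3), or VQ28 from the VQ family, and setting the lines against separate WT libraries, were chosen after seeing the data; the other alternatives were planned. The number of changed genes depended most on the tool and on single libraries, and the causes were not tested beyond fewer samples or fewer genes where the setting itself gives that. For VQ28KO12 against WT the count of 1 became 39 with DESeq2, and 3 with limma on log2(FPKM + 1), with a pseudocount of 5 and with units divided by 4. It became 5 with quantile normalization and with sample weights, and 2 without a filter or with only the 6 samples compared. At a mean FPKM of at least 5 it was 0, because that filter leaves out AT3G42658.1 before testing. Of the 10604 genes then tested, 549 had an unadjusted p under 0.05 by edgeR, where chance gives a share of 0.05. For VQ28OE9 against WT the count of 370 became 1358 with DESeq2, which held all 370, 728 with sample weights, 163 with only the 6 samples and 238 at a change of at least 1 on the log2 scale. For VQ28OE9 against VQ28KO12 the count of 1016 became 1957 with DESeq2 and 552 at a change of at least 1. The test planned for FPKM alone, limma on log2(FPKM + 1), called 472 genes in VQ28OE9 against WT and 1008 between the lines. Leaving out 1 library gave 1 to 4, 46 to 337 and 131 to 1241 genes in these 3 comparisons. With limma at a pseudocount of 5, 70.9% of the calls in VQ28OE9 against WT were higher, against 59.5%.

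VQ28 in VQ28KO12 against WT changed sign, never past the threshold: -0.021 with limma on log2(FPKM + 1), -0.648 at a pseudocount of 0.1, -0.0406 with quantile normalization, and -0.44 to 0.73 with 1 library left out. Against WT and against VQ28KO12, VQ28OE9 gave 9.49 to 10.6 and 9.30 to 10.5 with 1 library left out. The number of lists called by camera went from 7, 10 and 8 to 0, 0 and 0 with an estimated correlation, and ranged over 2 to 11, 9 to 11 and 8 to 10 with 1 library left out. The correlation of the lines' changes was 0.0601 at a mean FPKM of at least 5, 0.159 to 0.369 with 1 library left out, and -0.0714 on average with separate WT libraries. With terms of 20 to 200 genes, the GO terms passing fell from 4 to 2 (higher) and 5 to 2 (lower) in VQ28OE9 against WT, and from 31 to 19 (higher) and 18 to 13 (lower) in VQ28OE9 against VQ28KO12. The terms lost against WT, of 202 and 338 genes (higher) and 13, 246 and 11 genes (lower), lie outside that window. So do those of 10, 301, 246, 13 and 16 genes among the lower terms between the lines. Such falls follow from the window and do not measure how stable the terms were. No named gene other than VQ28 changed sign. They stayed on the same side of the threshold in 1379 results, lost the call in 148 and gained it in 15. The 1379 include genes that were not called in the main test, so they do not measure how stable the calls were. Without the libraries that stand apart, VQ28 in VQ28OE9 against WT gave 10.2 and lost its call (adjusted p = 0.0786).

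With a replicate block, 1, 468 and 1055 genes changed in the 3 comparisons. The labels do not say whether same-numbered libraries shared a batch. Deviations of same-numbered libraries from their genotype means correlated between -0.2 and 0.31, with 4 of 9 pairs over 0.1. For libraries with other numbers they correlated between -0.33 and 0.31. The highest same-numbered value, 0.31, was that of WT replicate 3 and VQ28OE9 replicate 3, the libraries that stand apart. These overlapping ranges cannot decide, so a shared batch stays open. Units divided by 4 gave 398 and 1063 genes in VQ28OE9 against WT and against VQ28KO12, leaving out organelle genes 374 and 1022, leaving out genes with a gap 401 and 1066, and leaving out the libraries that stand apart 94 and 1058. Depth limits low genes: 1 fragment is about 4 units, so folds of genes near 12 units rest on few fragments.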

Other observations

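The tests of label swap, spill-over and counting loss for VQ28, of genotype for the gaps between replicates, and of the epidermis share, were chosen after the results were seen; the others were set before, except that the simulation that decides on sampling noise was chosen after both had been seen. In the libraries labelled VQ28KO12, the starch-related gene QQS stood at 12.5 ± 1.38 FPKM (SD, n = 3) against 0.771 ± 0.473 in WT, a log2 fold change of 3.94 that did not pass (edgeR adjusted p = 0.399). The flowering repressor gene FLC stood at 1.17 ± 0.546 against 6.33 ± 1.097 FPKM, a log2 fold change of -2.49 (0.0898). Both genes were chosen after their values were seen.

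VQ28 had 525, 27 and 368 units in the WT libraries, and 546, 558 and 0 in those labelled VQ28KO12. If the knockout lacks VQ28 mRNA, a swap of libraries between these groups as the whole cause would leave 3 of the 6 libraries low, but 2 had VQ28 at under 0.1 of the highest, which argues against it. A swap of WT replicate 2 with VQ28KO12 replicate 1 or 2 as part of the cause cannot be told apart. AT3G42658.1 (0 units in each WT library, then 681, 402 and 760) and QQS (28, 53 and 15, then 646, 462 and 653) go against it but were chosen for following the labels. Of all tested genes with at least 200 units on the high side, 2 part these 6 libraries by over 10 times along the labels and 1 along the swapped labels (3 and 1 at over 5 times). Splits along neither also reached up to 1 gene at both ratios, so the gene along the swapped labels is no sign of a swap. At over 3 times such a split reached 3 genes, as many as the labels. AT4G32208, 1 of the 2 genes along the labels, also had a gap within VQ28OE9 (236, 0 and 439 units), so its counts are uncertain. Over the tested genes WT replicate 2 correlated at 0.974 with VQ28KO12 replicate 2, against 0.972 and 0.96 with WT replicates 1 and 3. Differences this small do not decide on a swap. Reads spilled over from VQ28OE9, of whose units WT replicates 1 and 3 and VQ28KO12 replicates 1 and 2 held 0.14% on average, could not be tested, because 0 other genes read only in VQ28OE9 were deep enough. Loss of a gene's reads in the counting of single libraries may play a part, since 74 genes had a gap of over 10 times between replicates, but VQ28 overlaps no other gene model and the explanations left cannot be told apart, with a knockout that keeps its mRNA untested.

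Those 74 genes, among them GT72B1 and EXO70H7, had a gap in WT (40), VQ28KO12 (25) or VQ28OE9 (30), with at least 200 units on the high side. Of them 40.5% overlap another gene model, against 17.1% of the other tested genes, an odds ratio of 3.25 at matched level (95% interval 1.97 to 5.30), which is consistent with reads moved between overlapping models in the authors' counting for part of them. Sampling noise at the dispersion of genes at the same level is argued against, since counts simulated with it gave 0 such genes. Those with gene-wise dispersion, which these gaps themselves raise, gave 29.3. That number met neither of the bounds set before, so a wider spread of single genes between libraries is not excluded. Genotype as the whole cause is argued against, since 40 of the genes had a gap within the WT libraries, which carry neither change of VQ28. A line in which single genes vary more stays open and untested. Some related gap genes that overlap no other model were low in the same library. In WT replicate 3 bHLH38, bHLH39 and BHLH100 had 32, 17 and 12 units, against 976, 419 and 772 in replicate 1. They were picked after their values were seen, and a difference between the sampled leaves was not tested. Without the 74 genes 401 genes changed, 367 of them among the 370.

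ATML1 was lower in VQ28OE9 than in WT, and 2 of the 5 guard cell markers, HT1 and FAMA, were higher, with adjusted p = 0.26 with an estimated correlation for the list. A lower share of epidermis in the sampled leaves would lower guard cell markers by about as much as the 2 tested epidermis markers, whose median log2 fold change was -0.74. The guard cell median was 0.78, with an SD of 0.62 over the 5 members, 3 above 0 and 2 below. A lower epidermis share alone would not raise HT1 and FAMA, which argues against it as the whole account for these 2 genes. For the other markers the test cannot decide. Only 2 epidermis markers were tested, with an SD of 0.66, and the guard cell values themselves prompted the question. In VQ28KO12 against WT the guard cell median was 0.40, and between the lines it was 0.22 with 0 of the 5 changed while ATML1 differed by -1.69, so a part of the difference may lie in the shared WT libraries. A change in guard cells alone stays open and untested.

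The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. VQ28OE9 against WT gave 370 changed genes and at most 0 in another split, so 1 split reached the real count. VQ28OE9 against VQ28KO12 gave 1016 and at most 1, again with 1 split, and VQ28KO12 against WT gave 1 and at most 2, with 5 splits at or above the real count. For lists called by camera with a preset correlation, the real counts of 10, 8 and 7 stood beside 12, 10 and 11 in the highest of the other splits, and 3, 4 and 4 splits reached the real count.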
